A study of Homo sapiens with 16 samples.

How the data were processed

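RNA was measured in 2 human cell lines with the NanoString nCounter, which counts colour-barcoded probe pairs bound to RNA molecules, with no amplification step. GM05757, a line of normal fibroblasts, was kept at 0% oxygen (anoxia) or in normoxia for 24 h, in medium with 15% serum. DU145, a prostate cancer line, was kept at 0.2% oxygen (hypoxia) or in normoxia for 72 h, in medium with 10% serum. The titles of the DU145 samples name 24 h and anoxia, whereas their descriptions, characteristics and treatment protocol name 72 h and hypoxia; the protocol was followed. Each condition of each line gave 4 libraries: total RNA, and pools from a sucrose gradient holding mRNAs with 0 to 3, with 4 to 7, and with 8 or more ribosomes. There were 16 libraries, 1 per line, condition and pool. The line, the oxygen level and the duration differ together between the 2 treated arms, so their effects cannot be separated.

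The authors deposited a table of raw counts for 230 probes: 6 positive controls, 8 negative controls, 2 spike-in RNAs (Arabidopsis and luciferase) and 214 probes for human genes. They also deposited a normalized signal for each probe and library, which the labels call NanoString counts normalized by positive and negative controls for total RNA and across fractions for the polysome pools. No software is stated in the labels. Comparing both tables showed how the signal was made. In every library the deposited signal equalled a factor times the raw count minus a background, with values below 0 set to 0, and the background was the mean plus 2 SD of the 8 negative controls (largest residual 0.000186 signal units). For total RNA the factor made the geometric mean of the positive controls equal in both libraries of a line (442 in GM05757 and 464 in DU145). For the polysome pools the factor made the geometric mean of the 2 spike-in probes equal over the 3 pools of a condition. If spike-ins were added and recovered equally over the 3 pools, pool values can be compared within a condition, and shares between conditions. The deposited pool levels cannot be compared between conditions. The largest factors were those of the DU145 pools of 0 to 3 ribosomes, 10.5 in hypoxia and 3.65 in normoxia. Per the labels' protocol, spike-in RNAs were added to the pools before precipitation; when they were added to total RNA is not stated.

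Genes were named by probe accession through a RefSeq gene table (GRCh38.p14), which matched 210 of the 214 probes; 4 kept the name in the file (ATM, PPP5C, RNF8 and Cyclin A1). The probe called CHOP carries the accession of another gene and was not taken for CHOP. The probe called hSSB1 carries that of SSBP1, and BACH1 here is the transcription factor. MXI1 has 2 probes for different isoforms, kept apart as SR alpha and SR beta. No coordinates are given, because the files name no genome build.

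Abundance was the log2 ratio of the deposited total RNA signals, low oxygen over normoxia. A gene was used where it lay above the background limit in at least 1 of the 2 libraries. The limit planned was the mean plus 2 SD of the negative controls on the scale used. The deposited signal sets every negative control to 0, so the limit was taken as the library's factor times its background. Values under the limit were set to it, and such ratios are bounds, written as at least so many fold; no fold is given where the bound is under 1. Translation was described by the heavy share, the percent of a gene's signal, summed over the 3 pools, that lay in the pool of 8 or more ribosomes. A gene was used where that sum exceeded 3 background limits in both conditions. Thresholds were a 2-fold ratio and 10 percentage points of heavy share. The panel median shifted by more than 0.1 log2 under other scalings, so genes and lists are reported relative to the median of all genes used, after that median is given.

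With 1 library per line, condition and pool there was no replicate spread, no test and no p-value. Intervals are 95% intervals from 10000 Poisson draws of the raw counts; they cover counting error only and leave out culture, gradient and RNA recovery. Raw counts over the human genes ran from 271237 to 1435409 per library, and 189 to 207 genes lay above the limit in each. 16 gene lists were fixed before the data were examined. Each list with at least 3 measured members is described by its median and by the percentile of that median among 10000 random lists of the same size drawn from the panel and matched on tertiles of expression. This percentile describes these libraries, and the panel itself is rich in repair genes. The lists of epithelial and of mesenchymal markers have 0 members on the panel, and the list of direct reversal has 1 (MGMT), so these were not summarised. The list of transcripts induced by DNA damage is named for what its members can respond to, and DNA damage itself was not measured. Named genes followed a rule fixed beforehand. It took the 10 largest increases and the 10 largest decreases of each comparison on the deposited scale with an interval that excludes no change, and 20 genes named for their role. It also took the extreme members of each list and the genes with opposite changes of at least 1.5-fold in the 2 lines. Some genes that the rule takes, 1 gene on opposite sides in the 2 lines, and the list of mismatch repair, are left out of the account, though they stay in every count and median. Genes named outside this rule are said to be so.

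Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated counts with 60 genes altered by known folds. Abundance was checked for genes above 2 background limits in both simulated libraries, 196 of 204 in GM05757 and 204 of 209 in DU145. Of their intervals, 96.4% in GM05757 and 95.1% in DU145 held the true log2 ratio. The median absolute error was 0.047 in GM05757 and 0.031 in DU145. Genes nearer to background were not checked. The median absolute error of the change in heavy share was 0.917 points for GM05757 (196 genes) and 0.605 points for DU145 (204 genes). The simulated counts held counting error only, and no shift of total RNA or heavy share common to the panel. These coverages and errors therefore do not extend to the panel shifts described below. Of 60 simulated lists without a shift, 2 in GM05757 and 1 in DU145 fell outside the central 95% of random lists. Of 20 lists with a shift of 1.5 log2, 20 in GM05757 and 19 in DU145 were found. Smaller shifts, such as those of the repair lists below, were not simulated.

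Alternatives fixed beforehand for abundance were centring on the panel median, scaling by reference genes, raw counts, no background filter, a limit of 50 counts, a gene above background in both libraries, and a pseudocount of 20. Those for translation were the share of 4 or more ribosomes, the mean number of ribosomes (1.5, 5.5 and 9 for the 3 pools, with a threshold of 0.75), centring, raw counts, equal sums of the pools, no filter, a sum of at least 300, and the 8 or more ribosome pool over total RNA. Correlations were repeated by rank, without the 10 genes farthest from the median, and with genes of at least 50 counts only. List percentiles were repeated unmatched, with means, and without shared members. Further alternatives were chosen after seeing the data: spike-in scaling of total RNA, the sum of the 3 pools in place of total RNA for genes and lists, a limit in all 4 total RNA libraries for the overlap of the lines, each spike-in probe alone, leaving out the 0 to 3 pool, log2 odds of the heavy share, and a partial correlation. For the sum of the pools, the spike-in means of both conditions of a line were first brought to the same level. Its panel median rests on equal addition of spike-ins in both conditions, which the labels do not state. Values relative to that median do not, but they rest on the spike-in scaling of the 3 pools within each condition. In DU145 the 2 spike-in probes disagreed in the normoxia pool of 0 to 3 ribosomes. A fit without spike-ins, also added after seeing the data, wrote each total RNA library as a non-negative sum of the 3 pool libraries, with intervals from resampling genes.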

Results

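The study compared mRNA abundance and translation of DNA damage response and repair genes in low oxygen and in normoxia. Transcripts of 214 human gene probes were counted in GM05757 fibroblasts after 24 h of anoxia (0% oxygen) or normoxia, and in DU145 prostate cancer cells after 72 h of hypoxia (0.2% oxygen) or normoxia. For each line and condition, 1 library was made from total RNA and 1 from each of 3 pools of a sucrose gradient, holding mRNAs with 0 to 3, 4 to 7, or 8 or more ribosomes. The total RNA libraries held 609259 raw counts over the human genes in GM05757 anoxia and 703756 in normoxia, and 458100 in DU145 hypoxia and 919186 in normoxia. The pool libraries held 271237 to 1435409. GAPDH took 28.9% of the counts of the GM05757 anoxia total and 23.3% of the DU145 hypoxia total, and ACTB took 25.7% and 12.5% of the normoxia totals of these lines. No library has a replicate, so the differences below compare libraries, and the intervals given cover counting error at the 95% level.

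In GM05757 fibroblasts without oxygen, the transcripts that stood highest above the rest of the panel were those of the low-oxygen response. CA9, a carbonic anhydrase of hypoxic cells, was at least 73.0-fold higher relative to the panel median (467 raw counts in anoxia and 19 in normoxia, where it lay at the background limit). DDIT4, an inhibitor of mTOR signalling, was 15.3-fold higher (log2 3.93, interval 3.81 to 4.06). SLC2A1, a glucose transporter, was 11.4-fold higher, and VEGFA, the angiogenic growth factor, 9.83-fold. At the other end stood transcripts of damage signalling and repair: the replication stress kinase ATR was 4.40-fold lower (43 raw counts and 306; log2 -2.14, interval -2.92 to -1.57), and the end-joining ligase LIG4 was lower by a log2 of -2.02 (-2.80 to -1.45).

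On the deposited scale nearly the whole panel was lower in the GM05757 anoxia library. The median of 205 genes was -1.41 in log2 (-1.48 to -1.39), 2.65-fold lower, with 148 genes at least 2-fold lower and 8 at least 2-fold higher. Scaling by the spike-in probes, chosen after seeing the data, put the median at 0.058, with 22 genes higher and 13 lower. Relative to the panel median, 22 genes were at least 2-fold higher and 19 at least 2-fold lower. Of the 205 genes, 6 lay at the limit in anoxia and 2 in normoxia, so their ratios are bounds. A gene near background in both libraries has a ratio near that of the 2 limits, which lies above the panel median.

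Of 7 measured hypoxia-induced transcripts in GM05757, 6 were at least 2-fold above the panel median and 1 at least 2-fold below. The list median was 3.30, above every random list (percentile 100). BNIP3, a mitophagy receptor, stood at 3.06 (3.02 to 3.10) and the glycolytic enzyme GAPDH at 2.28 (2.27 to 2.29). The member below was HIF1A, which encodes the oxygen-regulated transcription factor subunit, at -1.05 (-1.10 to -1.01). Outside the list, both probes of MXI1, a MYC antagonist, stood at 3.75 and 3.63, the AMP-activated kinase subunit PRKAA2 at 2.82 (2.27 to 3.52) and the endoplasmic reticulum oxidase ERO1A at 2.29 (2.23 to 2.35). All 4 members of the unfolded protein and integrated stress response list lay above the panel median (0.55, percentile 96.1), led by the phosphatase subunit PPP1R15A at 1.73 (1.59 to 1.88). All 6 usual reference genes lay above it as well (0.76, percentile 93.4). Without GAPDH, which is also in the hypoxia-induced list, they stood at 0.72 (percentile 88.6).

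Repair by homologous recombination had the lowest median of the repair lists in GM05757 total RNA. Of its 23 measured members, 18 lay below the panel median, 6 by at least 2-fold, and 1 lay at least 2-fold above; the list median was -0.62, at percentile 0.26. The helicase BLM stood at -1.40 (-2.26 to -0.74), the double-strand break sensor NBN at -1.36 (-1.61 to -1.13) and the nuclease EXO1 at -1.21 (-1.58 to -0.88). BRCA1 stood at -0.79 (-1.18 to -0.43), BRCA2 at -0.73 (-1.28 to -0.27) and XRCC3 at -0.68 (-1.07 to -0.33). RAD51B was the member above, at 1.15 (0.81 to 1.48). For damage sensing and checkpoint signalling, 16 of 19 members lay below the median, 6 by at least 2-fold (-0.61, percentile 0.405), among them CLSPN, a mediator of ATR signalling, at -1.98 (-2.34 to -1.65), the phosphatase CDC25A at -1.55 and TP53BP1 at -1.31. ATM stood at 0.10 (-0.19 to 0.38), CHEK1 at -0.65 and CHEK2 at -0.61. The 2 lists share members; without these their percentiles were 4.59 and 10.4. In the sum of the 3 pools, used as a second measure of abundance after seeing the data, homologous recombination stood at -0.24 (percentile 2.98) and checkpoint signalling at -0.15 (percentile 20.005). There BRCA1 stood at -0.08, BRCA2 at 0.15 and CHEK2 at 0.01, so the low values of these 3 genes in total RNA were not repeated. XRCC3 stood at -0.89, LIG4 at -0.98, ATR at -1.32 and CDC25A at -1.22. BLM (-0.24), NBN (-0.57), EXO1 (-0.91), CLSPN (-0.71) and TP53BP1 (-0.44) stayed below the median, but by less than 2-fold.

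In GM05757 total RNA, of 15 Fanconi anaemia genes, 13 lay below the panel median (-0.47, percentile 5.22), FANCM lowest at -1.47 (-2.17 to -0.71) and FANCD2 at 0.01. The mean of the Fanconi list was -0.51 (percentile 1.32), and in the sum of the pools it stood at -0.37 (percentile 2.08), but without members shared with another list at -0.38 (percentile 14.01). Of 9 genes of proliferation and S phase, 6 lay below (-0.62, percentile 2.20; -0.27 and percentile 3.83 in the sum of the pools), with the cyclin CCNA2 at -1.03 (-1.11 to -0.94). The mismatch repair genes MSH6 and MLH3 stood at -0.54 (-0.75 to -0.35) and 0.86 (0.56 to 1.14). Non-homologous end joining stood at -0.11 (percentile 36.0), with PRKDC at -0.65 but at 0.09 in the sum of the pools. Base excision repair stood at -0.05 (percentile 53.6), translesion synthesis at -0.10 (percentile 55.1) and nucleotide excision repair at 0.03 (percentile 62.9). Transcripts induced by DNA damage stood at 0.30 (percentile 82.2), with the growth arrest genes GADD45A at 0.91 (0.83 to 0.99) and CDKN1A at 0.55 (0.52 to 0.59). The alkyltransferase MGMT stood at 0.67 (0.53 to 0.81). In the sum of the pools, transcripts induced by DNA damage stood at 0.04 (percentile 58.6), with GADD45A at 0.58 and CDKN1A at 0.12. Base excision repair stood there at -0.21 (percentile 14.3), nucleotide excision repair at -0.05 (percentile 40.3), non-homologous end joining at 0.05 (percentile 65.6), translesion synthesis at 0.35 (percentile 88.2), the stress response list at 0.51 (percentile 96.7) and the reference genes at 0.38 (percentile 76.7). The interferon-inducible SAMD9L was at -1.90 (-2.57 to -1.17).

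In DU145 cells at 0.2% oxygen, the same kind of transcripts led the panel, and most genes of homologous recombination and the Fanconi pathway lay below its median. BNIP3 was 11.3-fold higher relative to the panel median (log2 3.50, interval 3.46 to 3.54), SLC2A1 10.9-fold and VEGFA 8.98-fold. BRCA1 was 4.62-fold lower (59 raw counts in hypoxia and 1033 in normoxia; log2 -2.21, interval -2.74 to -1.77). CDKN1A, an inhibitor of cyclin-dependent kinases, was 4.06-fold higher relative to the panel median, though lower in hypoxia than in normoxia on the deposited scale.

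On the deposited scale the median of 208 genes in DU145 was -2.99 in log2 (-3.02 to -2.92), 7.93-fold lower, with 193 genes at least 2-fold lower and 0 at least 2-fold higher. The 6 probes with a ratio above 1 and an interval that excludes no change were both MXI1 probes (0.97 and 0.77), BNIP3 (0.51), SLC2A1 (0.45), VEGFA (0.18) and DDIT4 (0.17). Raw counts gave a median of -2.11, and scaling by reference genes gave -1.01. Relative to the panel median, 44 genes were at least 2-fold higher and 34 at least 2-fold lower. Of the 208 genes, 12 lay at the limit in hypoxia and 1 in normoxia, so their ratios are bounds. In DU145 too, genes near background in both libraries are placed above the low panel median by the limits.

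All 7 hypoxia-induced transcripts measured in DU145 lay above the panel median, 6 by at least 2-fold (3.15, percentile 100), with DDIT4 at 3.15 (3.10 to 3.21), GAPDH at 2.58 and HIF1A at 0.21 (0.15 to 0.27). CA9 lay near background in both libraries (29 raw counts in hypoxia and 15 in normoxia), and no fold is given for it. It is counted among the 6, but its place there rests on the background limit and on the low panel median. The MXI1 probes stood at 3.95 and 3.76. Among transcripts induced by DNA damage, 5 of 7 lay above the median (0.56, percentile 87.3), 3 by at least 2-fold: the phosphatase PPM1D at 2.34 (2.16 to 2.52), CDKN1A at 2.02 (1.93 to 2.11) and the BCL2 family gene BBC3 at 1.43 (1.25 to 1.60). The unfolded protein and integrated stress response list stood at -0.31 (percentile 20.2), with PPP1R15A at 1.38 (1.26 to 1.51) and the chaperone HSPA5 at -1.36 (-1.50 to -1.24). The 6 reference genes all lay above the median (1.21, percentile 92.4). Without GAPDH, which is also in the hypoxia-induced list, they stood at 0.83 (percentile 74.2).

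Of the 23 homologous recombination genes in DU145, 17 lay below the panel median, 9 by at least 2-fold and 0 at least 2-fold above (-0.62, percentile 1.56). EXO1 stood at -2.16 (-2.80 to -1.68), BLM at -1.66 (-2.53 to -1.09), the helicase WRN at -1.55 (-2.10 to -1.11) and XRCC3 at -0.94 (-1.15 to -0.73). BRCA2 stood at -1.23 (-1.74 to -0.81) in total RNA but at 0.12 in the sum of the 3 pools, which rests on the spike-in scaling of the pools. Of 15 Fanconi anaemia genes, 11 lay below, 6 by at least 2-fold (-0.90, percentile 1.11), with FANCD2 at -1.86 (-2.32 to -1.50) and FANCA at -1.19 (-1.70 to -0.78). In the sum of the pools homologous recombination stood at -0.76 (percentile 1.47) and the Fanconi anaemia genes at -0.72 (percentile 8.21). The mismatch repair genes PMS2, MSH6 and MLH3 stood at -1.22 (-1.56 to -0.92), 0.25 and 1.01. Proliferation and S phase stood at -0.48 (percentile 4.8), but at -0.02 (percentile 32.5) in the sum of the pools, with PCNA at -0.77 (-1.06 to -0.50) and the cyclin CCND1 at 1.04 (0.97 to 1.10). Damage sensing and checkpoint signalling stood at -0.20 (percentile 36.3), with 14 of 20 members below; its mean was -0.41 (percentile 4.71), without shared members it stood at -0.38 (percentile 25.6), and in the sum of the pools at -0.12 (percentile 54.5). In that list CDC25A was at least 5.43-fold below the median. ATR stood at -1.26 (-1.65 to -0.94), CHEK2 at -0.59, ATM at -0.52 and CHEK1 at 0.16. Non-homologous end joining stood at 0.10 (percentile 62.4; 0.56 and percentile 94.1 in the sum of the pools), with the ligase cofactor NHEJ1 at 1.35 (1.11 to 1.58), LIG4 at -0.52 and PRKDC at -0.39, but PRKDC at 1.19 in the sum of the pools. Base excision repair stood at -0.22 (percentile 34.9), nucleotide excision repair at 0.09 (percentile 58.0) and translesion synthesis at -0.46 (percentile 39.2). MGMT stood at 0.73 (0.58 to 0.87). In the sum of the pools base excision repair stood at -0.01 (percentile 73.2), nucleotide excision repair at 0.25 (percentile 81.6), translesion synthesis at -0.13 (percentile 59.0), transcripts induced by DNA damage at 0.25 (percentile 77.2), the stress response list at -0.39 (percentile 15.02) and the reference genes at 1.13 (percentile 91.4). Also low were the histone gene H2AC20 at -2.99 (-3.11 to -2.89), the immediate-early gene EGR1 at -2.19, the chaperone HYOU1 at -2.15, and the insulin receptor substrate IRS1, at least 6.83-fold below.

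**Figure D1:**
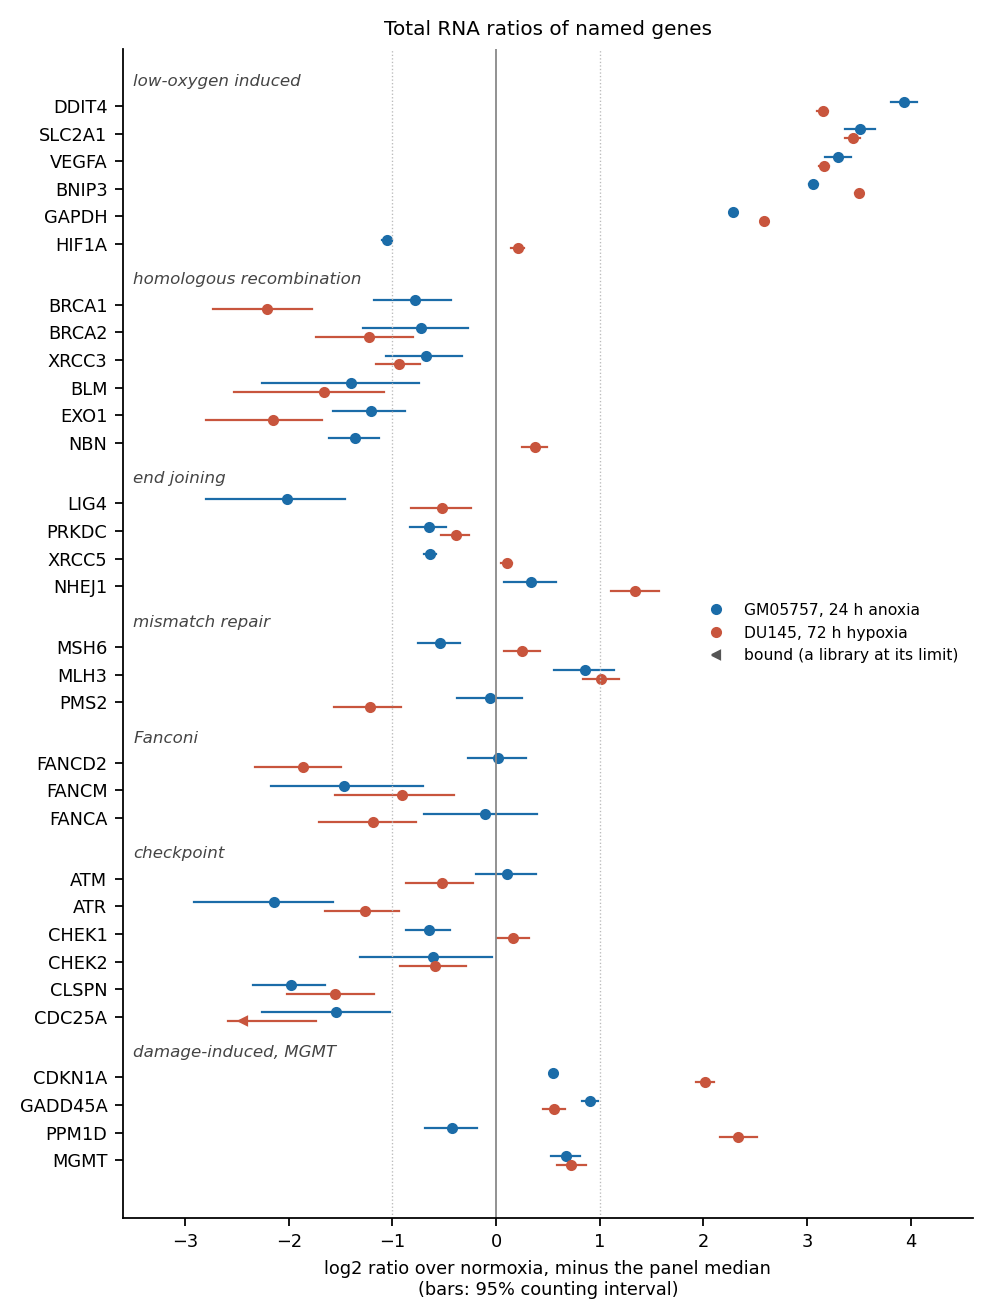
Log2 ratio of total RNA in low oxygen over normoxia minus the panel median (x axis) for named genes grouped by function (y axis), GM05757 in blue and DU145 in red; points are single library pairs, bars the 95% counting interval, and dotted lines mark 2-fold. DDIT4, SLC2A1, VEGFA and BNIP3 lie above 3 in both lines, and BRCA1 lies at -0.79 in GM05757 and -2.21 in DU145.

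Across the 202 genes measured in both lines, the log2 ratios of total RNA had a Pearson r of 0.617 and a Spearman rho of 0.504; genes are not independent replicates, and no p is given. Relative to each panel median, 15 probes were at least 2-fold higher in both lines, where independent lists of these sizes would share 4.57. They were CA9, DDIT4, both MXI1 probes, SLC2A1, VEGFA, BNIP3, GAPDH, ERO1A, P4HB, PPP1R15A, FOS, JUN, EGFR and TP73. At least 2-fold lower in both were ATR, BLM, CDC25A, CLSPN, EXO1 and GEN1, 6 genes where 3.03 would be shared. Members of these overlaps outside the naming rule are listed because the counts are small. CA9, TP73 and CDC25A had at least 1 library at its background limit. Among the 188 genes above the limit in all 4 total RNA libraries, a filter chosen after seeing the data, 13 were higher in both lines where 3.84 would be shared, and 5 lower where 2.53 would be. The sum of the 3 pools gave a second measure of abundance, whose ratios correlated with those of total RNA across genes with an r of 0.925 in GM05757 and 0.933 in DU145. Of the genes at least 2-fold from the panel median, 41 of 41 in GM05757 and 74 of 75 in DU145 lay on the same side of it in the sum of the pools. Of the genes nearer to the median, 123 of 160 and 106 of 130 did. The 6 genes lower in both lines stayed below the median there, but only CDC25A by at least 2-fold in both. Of those higher in both, FOS, JUN and TP73 in GM05757 and PPP1R15A in DU145 were under 2-fold there, and CA9 was not measured in DU145.

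**Figure D2:**
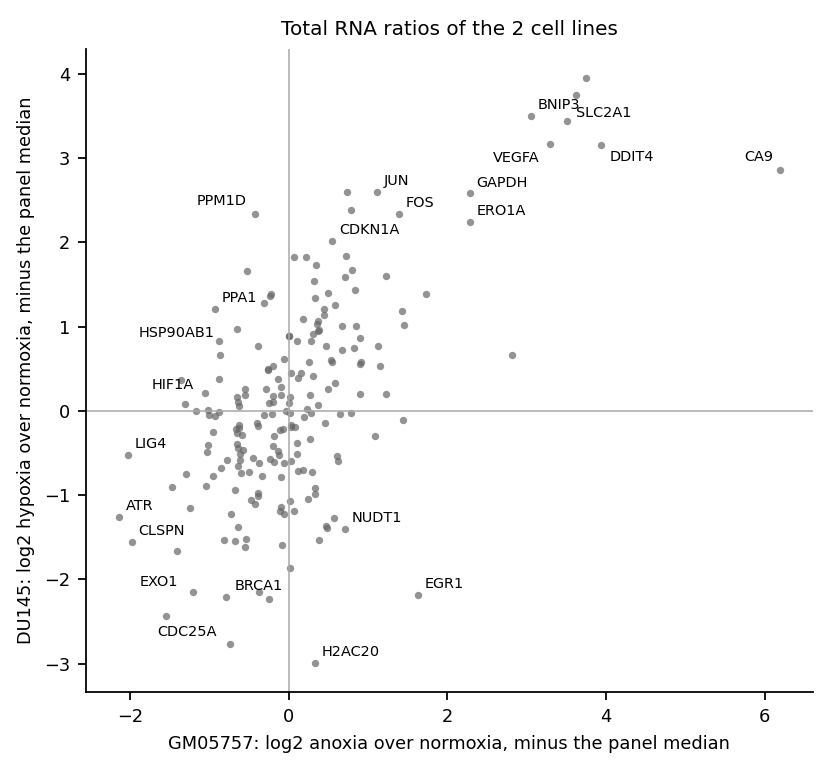
Log2 ratio of total RNA in low oxygen over normoxia minus the panel median, for GM05757 (x axis) and DU145 (y axis); each point is 1 of 202 genes measured in both lines. BNIP3, SLC2A1, VEGFA and DDIT4 lie at the upper right (r across genes 0.617), while EGR1 lies at 1.63 in GM05757 and -2.19 in DU145.

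Polysome pools of GM05757 held less of the panel's summed signal in the heaviest pool under anoxia, though 34.0% of 194 genes had a higher heavy share. The pool of 8 or more ribosomes held 34.3% of the summed signal in anoxia and 44.4% in normoxia, and the pool of 0 to 3 ribosomes 36.8% and 19.3%. These sums lean on abundant genes. GAPDH took 38.9% of the counts of the anoxia pool of 0 to 3 ribosomes and 32.5% of the anoxia heavy pool. ACTB took 36.2% of the normoxia heavy pool. EPAS1, which encodes the HIF-2 alpha subunit, had 63.0% of its mRNA in the heavy pool in anoxia and 17.8% in normoxia, 45.2 points more (42.8 to 47.5). VEGFA had 49.7% and 34.2%, 15.5 points more (12.6 to 18.5). The chaperone HSP90AB1 had 48.1% and 81.8%, a difference of -33.6 points (-35.0 to -32.3), and the adhesion receptor CD44 36.6% and 66.9%.

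Over 194 GM05757 genes the median change of heavy share was -4.70 points (-5.00 to -3.17); 57 genes were at least 10 points lower and 5 at least 10 points higher. The 5 higher were EPAS1, VEGFA, both MXI1 probes (20.4% and 9.45%; 21.1% and 10.4%) and the checkpoint clamp gene RAD9A (19.6 points more, 4.96 to 36.9). PRKDC, the catalytic subunit of the DNA-dependent kinase, had 73.2% and 65.0%, a difference of 8.18 points (2.77 to 13.7). Lower were also BLM (29.9% and 58.4%), the corepressor TRIM28 (53.4% and 79.7%) and the nuclease MRE11 (45.9% and 70.5%). CHEK1 had 30.7% and 41.3%, FANCD2 59.9% and 72.1%, and MSH6 68.4% and 81.9%. The interval of the difference included 0 for BRCA1 (31.5% and 38.0%), BRCA2 (17.8% and 27.3%), ATM (15.6% in anoxia) and ATR (57.8% and 66.8%). CDKN1A had 12.2% and 9.71%, GADD45A 15.2% and 9.23%, and MGMT 20.1% and 17.6%.

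Relative to the panel median change in GM05757, nucleotide excision repair stood at -8.98 points (percentile 2.02, but 14.9 by the mean and 15.3 without shared members), with the damage sensor XPC at 52.7% and 71.4%. Non-homologous end joining stood at -3.04 points (percentile 20.4), with the Ku subunits XRCC5 at 59.5% and 80.8% and XRCC6 at 54.3% and 72.7%, while LIG4 had 33.1% and 52.7% (interval -35.9 to 0.169). Homologous recombination stood at -2.28 (percentile 13.8), the Fanconi anaemia genes at -2.28 (percentile 18.4), checkpoint signalling at -2.07 (percentile 22.2), base excision repair at -1.92 (percentile 36.0) and proliferation at -1.49 (percentile 26.1). Without members shared with another list, the Fanconi anaemia genes stood at -7.01 (percentile 3.20) and checkpoint signalling at 0.56 (percentile 67.6). Transcripts induced by DNA damage stood at 4.49 (percentile 75.3), the stress response list at 3.28 (percentile 80.5), the reference genes at 2.86 (percentile 51.5) and the hypoxia-induced transcripts at -1.60 (percentile 21.6). For the last 2 the mean had the opposite sign (-0.63 and 1.25).

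The GM05757 panel median was positive without the spike-in scaling of the pools, 6.54 points with raw counts and 3.31 with equal sums. With the 0 to 3 pool left out it was -0.036 points, with 15 genes at least 10 points higher and 21 lower, and a fit without spike-ins placed 33.6% of the anoxia library (29.9 to 37.4) and 48.9% of the normoxia library (45.7 to 52.1) in the heavy pool; both were chosen after seeing the data. With the heavy pool over total RNA in place of the share, BLM, MRE11 and XRCC5 stood above the panel median (0.21, 0.044 and 0.016 in log2), and EGR1 and JUN below it (-0.21 and -0.20), whereas their heavy shares stood on the opposite side.

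In DU145 at 0.2% oxygen most of the panel's summed signal lay in the lightest pool, and 10.2% of 197 genes had a higher heavy share than in normoxia. The pool of 8 or more ribosomes held 9.59% of the summed signal in hypoxia and 35.9% in normoxia, and the pool of 0 to 3 ribosomes 81.3% and 40.9%. In the normoxia pool of 0 to 3 ribosomes, the Arabidopsis spike-in stood 8.22-fold over the luciferase one, against 2.66 and 2.65 in the other normoxia pools. A fit without spike-ins, chosen after seeing the data, gave 66.4% and 18.2% for the pool of 0 to 3 ribosomes. XRCC5 had 26.1% of its mRNA in the heavy pool in hypoxia and 80.6% in normoxia, a difference of -54.6 points (-55.5 to -53.6). The mitotic cyclin CCNB1 had 13.7% and 66.6%, and PARP1, the sensor of DNA strand breaks, 28.2% and 80.3%. Against this, ATR had 52.4% and 30.0%, 22.4 points more (15.7 to 29.7), VEGFA 44.8% and 28.4%, 16.4 points more (15.5 to 17.3), and PRKDC 49.0% and 36.5%, 12.5 points more (9.57 to 15.4).

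Over 197 DU145 genes the median change of heavy share was -14.7 points (-15.8 to -13.9); 120 genes were at least 10 points lower and 4 at least 10 points higher. The 4 higher were ATR, VEGFA, PRKDC and the helicase RECQL4 (29.7% and 11.9%, interval of the difference 6.85 to 39.5). With a pool sum of at least 300 required, 3 of 192 genes were at least 10 points higher. The background subtracted in hypoxia was 166 signal units in the pool of 0 to 3 ribosomes and 21.8 in the heavy pool. For genes with few counts this can raise the hypoxia heavy share, and the intervals cover counting error only. Smaller positive differences were found for the replicative polymerase POLE (29.7% and 22.3%), ATM (28.4% and 21.1%), LIG4 (38.7% and 32.4%), VHL (14.8% and 9.28%) and TP53BP1 (44.1% and 39.9%). Lower were HSP90AB1 (20.5% and 71.8%), the retinoblastoma gene RB1 (11.1% and 62.4%), XRCC6 (21.8% and 71.0%), the chaperone CALR (21.9% and 70.5%), SLC2A1 (27.3% and 72.2%) and CHEK1 (14.9% and 46.1%). BRCA2 had 31.2% and 51.7%. The interval of the difference included 0 for BRCA1 (43.3% and 43.5%) and FANCD2 (38.8% and 40.1%). CDKN1A had 4.35% and 10.7%, and MGMT 6.38% and 21.8%.

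Relative to the panel median change in DU145, base excision repair stood at -9.35 points (percentile 3.58, with 7 of 11 members below). Proliferation and S phase stood at -13.3 (percentile 6.63, with 7 of 9 below), and nucleotide excision repair at -5.75 (percentile 21.3; 3.50 by the mean), with RPA1, a subunit of the single-strand binding complex, at 21.5% and 71.4%. Non-homologous end joining stood at -0.88 (percentile 34.7), where PRKDC and LIG4 lay above the median and both Ku subunits below. Homologous recombination stood at 0.54 (percentile 39.8), checkpoint signalling at -0.48 (percentile 41.3) and the Fanconi anaemia genes at 1.00 (percentile 48.6). The means of the first 2 of these had the opposite sign (-0.41 and 0.72). Without members shared with another list, checkpoint signalling stood at 8.02 (percentile 94.2). Transcripts induced by DNA damage stood at 4.93 (percentile 74.3), the stress response list at 1.78 (percentile 60.7), the reference genes at -4.72 (percentile 55.2) and the hypoxia-induced transcripts at -9.84 (percentile 37.1). A share that is low in normoxia can be lower by few points only. Pools set to equal sums gave a panel median of 7.54 points, and the 2 spike-in probes taken singly, chosen after seeing the data, gave -21.0 (Arabidopsis) and -8.07 (luciferase).

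**Figure D3:**
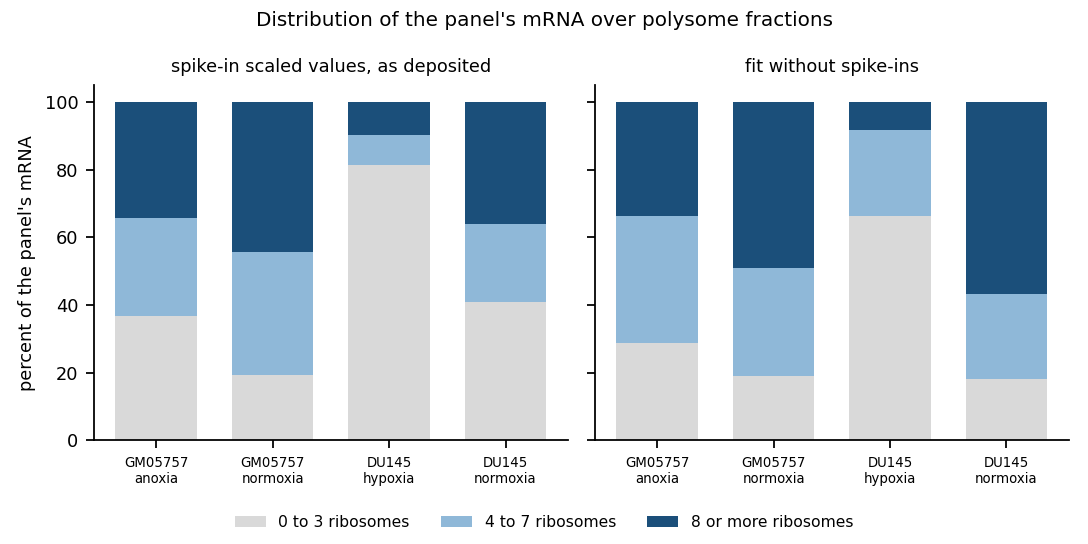
Percent of the panel's mRNA (y axis) in the pools of 0 to 3, 4 to 7 and 8 or more ribosomes for each line and condition (x axis), from the deposited spike-in scaled values (left) and from a fit of each total RNA library to its 3 pools that uses no spike-in (right). The heavy pool of DU145 is smaller in hypoxia than in normoxia in both panels, 9.59% and 35.9% on the left, 8.13% and 56.8% on the right.

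**Figure D4:**
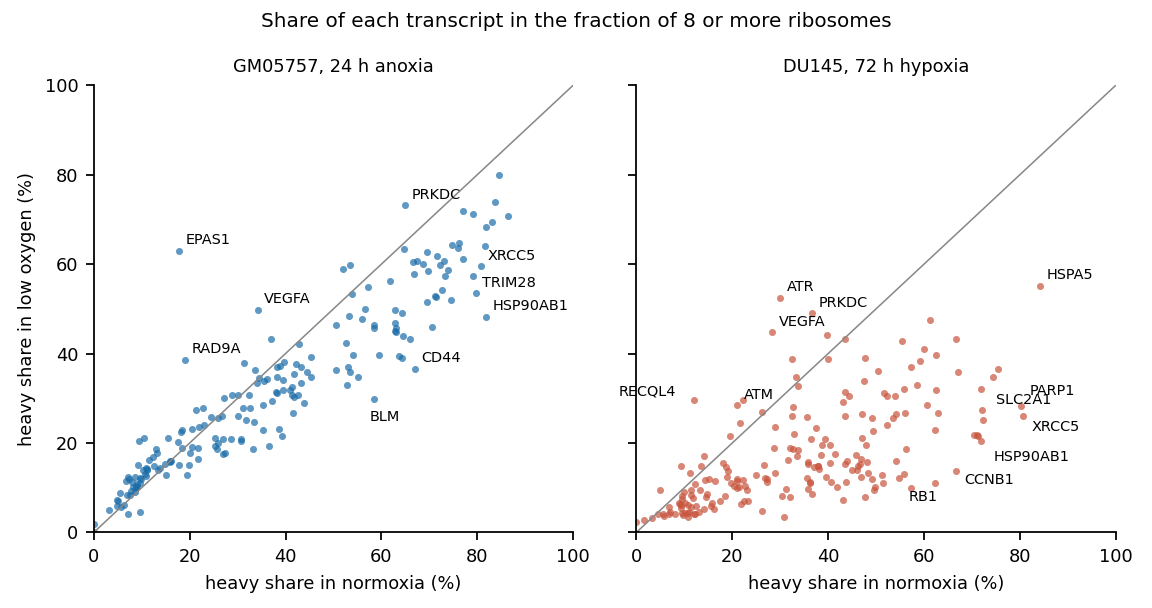
Heavy share of each transcript in low oxygen (y axis, percent) against normoxia (x axis, percent) for 194 genes of GM05757 (left) and 197 of DU145 (right); each point is a gene and the line marks equal shares. EPAS1 (63.0% and 17.8%) in GM05757 and ATR (52.4% and 30.0%) in DU145 lie above the line, and most points of DU145 lie below it.

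Across 189 genes measured in both lines, the changes of heavy share had a Pearson r of 0.506 and a Spearman rho of 0.531. The normoxia shares of the lines correlated with an r of 0.808, and given these the partial correlation of the changes was 0.299 (0.134 to 0.458, resampling genes). Relative to each panel median, 6 probes were at least 10 points higher in both lines, where independent lists would share 3.16: VEGFA, PRKDC, RAD9A, APTX and both MXI1 probes. The MXI1 probes and RAD9A have low shares in DU145 in both conditions. At least 10 points lower in both were 22 genes, where 10.9 would be shared, among them HSP90AB1, XRCC5, XRCC6, CCNB1 and XRCC1. These expected numbers take the lines as independent and make no allowance for their related normoxia shares. An overlap above them therefore cannot be told apart from an effect of those shares. Abundance and heavy share were weakly related across genes, with an r of 0.286 and a rho of 0.321 in GM05757 (194 genes) and -0.130 and -0.157 in DU145 (197 genes).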

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

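Apart from the raw counts, which were fixed beforehand as another scaling and read as a test later, the tests weighed in this part were chosen after the result was seen.

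Both treated total RNA libraries stood lower over nearly the whole panel on the deposited scale. In GM05757 the spike-in probes were lower in the anoxia library by as much, with a log2 of -1.46 against a panel median of -1.41, so a smaller amount of RNA loaded together with its spike-ins may account for the shift. In DU145 the spike-in probes were higher in the hypoxia library, with a log2 of 0.76, which argues against that explanation there; it also stood out because no comparison of the study uses these probes in total RNA. The raw counts gave medians of -1.12 in GM05757 and -2.11 in DU145, so the positive-control scaling alone does not produce either shift. Less cell RNA set against a fixed amount of spike-in, RNA quality and a true loss of these mRNAs under low oxygen stay open in DU145, since the labels do not say when the spike-ins were added to total RNA. In GM05757 the sum of the pools also gave a lower median, -1.09, with 114 genes at least 2-fold lower and 9 higher. Loading of the total RNA library cannot produce this, but the value rests on equal addition of spike-ins in both conditions. RNA quality and a true loss therefore stay open in GM05757 too.

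The heavy share of DU145 was lower in hypoxia across the panel, and its size depends on the spike-in probes of the 0 to 3 ribosome pool. With that pool left out, the median share of 8 or more ribosomes was still lower, by -6.26 points (-8.90 to -3.52 over genes). The spike-in probe that gives the smaller change, taken alone, gave -8.07 points. A fit of each total RNA library to its pools that uses no spike-in placed 8.13% of the hypoxia library in the heavy pool (6.19 to 10.5), against 54.6 to 58.9 in normoxia. These values argue against pool recovery or probe disagreement as the whole cause, but no test here could decide what the cause is. A lower ribosome load in hypoxia, degraded RNA and dying cells after 72 h stay open.

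Transcripts with a high heavy share in normoxia had the larger loss in both lines: the change correlated with a gene's own normoxia share across genes with an r of -0.70 in GM05757 and -0.81 in DU145. An error of the normoxia libraries would give such a relation, but with the normoxia share taken from the other line r was still -0.52 in GM05757 and -0.55 in DU145. The percent scale could also give it, but the change in log2 odds kept an r of -0.57 and -0.38 with the share of the other line. In 3 groups of about equal size, from low to high normoxia share, the median change was 1.80, -6.03 and -13.7 points in GM05757 and -3.86, -15.5 and -31.2 points in DU145. Both tests argue against these explanations as the whole cause. With the pools at equal sums, r with the share of the other line was smaller, -0.38 (-0.53 to -0.24) in GM05757 and -0.31 (-0.46 to -0.16) in DU145. The size of the relation thus depends on how the pools are scaled. A greater loss of ribosomes by mRNAs with a high heavy share in normoxia was not tested and stays open, with line, oxygen level and duration not separable.

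Genes that stood on opposite sides of the panel median in the 2 lines by at least 1.5-fold each way are given as values; none of these differences was tested. The difference of the relative total RNA log2 ratio, DU145 minus GM05757, was -3.81 for EGR1, -2.11 for the nucleotide pool enzyme NUDT1 and -1.22 for ATF4. It was 2.14 for the pyrophosphatase PPA1, 1.71 for HSP90AB1, 1.61 for ATRX and 1.53 for CDKN2A, whose GM05757 value is a bound at the limit. In the sum of the pools, ATF4 and ATRX lay on the other side in GM05757 (-0.39 and 0.67), and the remaining 5 lay on the same side as in total RNA in both lines. The difference of the relative change in heavy share was 36.0 points for LIG4, whose GM05757 interval runs from -31.2 to 4.87.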

How the results depend on the processing

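No paired analysis was possible because each line, condition and pool has 1 library, and for the same reason no library could be left out. Spike-in scaling of total RNA, the sum of pools, single spike-in probes, the share without the 0 to 3 pool, log2 odds and the partial correlation were chosen after seeing the data. For the 16 comparison results, 65 of 132 alternative values stayed within 1.5 times of a count or within the counting interval, 61 moved in size and 6 reversed. Of 1929 values for named genes 1206 stayed the same, 709 moved and 14 reversed, 3 of these only as bounds. A value counts as reversed only if the gene was at least 2-fold or 10 points from the panel median with an interval that excludes it. Of the 709 that moved, 58 lay on the other side of the panel median without meeting this. Of 176 list values 14 moved. Centring sets medians to 0 by construction, equal sums remove a shift shared by all genes, and the heavy pool over total RNA mixes separate scalings; for the other moves the cause was not tested.

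For GM05757 total RNA, centring gave 22 genes higher and 19 lower, reference gene scaling 62 lower and a median of -0.58, and spike-in scaling 22 higher, 13 lower and a reversed median of 0.058. The median was -1.12 with raw counts, -1.31 with a pseudocount of 20 and -1.09 in the sum of pools. With a limit of 50 counts FANCM stood at 0.094 at most, a bound set by the limit, which does not show a reversal. For DU145 total RNA, centring gave 44 higher and 34 lower, reference gene scaling 15 higher, 105 lower and a median of -1.01, raw counts 4 higher and -2.11, and no background filter 1 higher. The median was -2.88 with a limit of 50, -2.77 with a pseudocount of 20, -3.75 with spike-in scaling and -3.43 in the sum of pools. With a limit of 50, CDC25A stood at 0.13 and POLI at 1.04 at most, again bounds that show no reversal. In the sum of pools BRCA2 reversed to 0.12, and genes nearer to the median changed side, in DU145 PRKDC (1.19), FANCE and RNF8, in GM05757 ATF4, ATRX, BRCA2, CHEK2 and PRKDC.

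For the heavy share of GM05757, the share of 4 or more ribosomes gave 2 genes up, 109 down and a median of -11.1 points, with XPC reversed to 5.498. The mean number of ribosomes gave 2 up and a median of -0.60 ribosomes, and centring 14 up and 36 down. Raw counts gave 41 up, 4 down and a reversed median of 6.54, and equal sums 12 up, 13 down and 3.31. No filter gave 13 up. The heavy pool over total RNA gave 92 up, 0 down and a reversed median log2 of 0.98, with BLM (0.21), EGR1 (-0.21), JUN (-0.20), MRE11 (0.044) and XRCC5 (0.016) reversed. Without the 0 to 3 pool there were 15 up and 21 down with a median of -0.036, and log2 odds gave 34 down and -0.34.

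For the heavy share of DU145, the share of 4 or more ribosomes gave a median of -24.2 points, with HSPA5 reversed to 4.49, and the mean number of ribosomes -1.49. Centring gave 49 up and 60 down, raw counts 20 up and -5.65, and no filter 9 up and -13.7. Equal sums gave 80 up, 25 down and a reversed 7.54. The heavy pool over total RNA gave 164 up, 0 down and a reversed median log2 of 1.60, with DDB1 (0.20) and HSPA5 (1.13) reversed. The Arabidopsis probe alone gave 2 up and -21.0, the luciferase probe 8 up and -8.07. Without the 0 to 3 pool there were 20 up, 79 down and a median of -6.26, with SLX4 reversed to -7.95, and log2 odds gave -1.37. The correlation of heavy share changes between the lines was 0.299 as a partial correlation. Counts near background limit CA9, CDC25A and POLI in DU145.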

Other observations

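The genes in this part were chosen after their values were seen. The values are given without a test. Relative to the panel median of total RNA, the oxidase ERO1A stood at 2.29 in GM05757 and 2.25 in DU145, and its partner P4HB, a protein disulfide isomerase, at 1.43 and 1.19. The chaperone HSPA5 stood at 0.47 and -1.36, its cofactor DNAJB11 at -0.54 and -1.62, and HYOU1 at -0.37 and -2.15. Other folding genes of the panel stood at 0.79 and -0.03 (PDIA6), 0.59 and 0.33 (CALR), 0.29 and -0.02 (DNAJB9) and 0.03 and -0.60 (HSP90B1). Of the immediate-early genes, JUN stood at 1.12 in GM05757 and 2.60 in DU145 and FOS at 1.39 and 2.34, EGR1 at 1.63 and -2.19 and MYC at 1.44 and -0.10.

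The receptors EGFR and IGF1R stood at 1.23 and 0.68 in GM05757 and at 1.60 and 1.01 in DU145, while the adaptor IRS1 stood at -0.74 in GM05757 and at most -2.77 in DU145. The transcription factor BACH1 stood at 2.38 in DU145 and at 0.78 in GM05757. EPAS1 stood at 1.66 in DU145 total RNA with 20.9% of its mRNA in the heavy pool in hypoxia and 36.4% in normoxia, whereas in GM05757 it stood at -0.53 and had 63.0% in anoxia and 17.8% in normoxia.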
